A study of Homo sapiens with 12 samples.

How the data were processed

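RNA was measured by sequencing of poly-A selected libraries from 2 human cell lines, MCF7 and IMR90. Per the labels' protocols, cells were kept overnight without serum and were then left untreated or given EGF or dexamethasone (DEX) for 60 min. The libraries were made with a TruSeq version 2 kit, which does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. Each of the 6 groups (line by treatment) held 2 libraries, and groups were taken from the sample titles. The labels do not state whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

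The deposited table gave a signal for 21337 gene symbols in 12 libraries. Per the submitters' processing notes, STAR, DESeq2 and the hg19 build were used; the counter, the annotation and the versions are not given in the sources used here. The deposited signal of a gene is its read count divided by 1 size factor per library, as the authors' values showed: in every library 100% of the values were whole multiples of the value of 1 read, within 0.1 read, so whole reads were recovered. All 12 libraries lay on 1 common scale. The recovered totals were 18.5 to 23.5 M reads per library. Positions are not given, because the annotation at hand was of another build than hg19. Gene symbols are those of the deposited table.

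The test fixed before the data were examined assumed read counts and edgeR, with limma in its place if the table held normalised values; since it did, limma was used. Values were transformed to log2(value + 1), so fold changes of low genes are understated. Genes with a value of at least 10 in at least 2 libraries were kept (16142 genes). limma with a variance trend was fitted to all 12 libraries with a term per group (6 residual degrees of freedom before moderation), and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A call is a gene past that threshold. The comparisons were EGF and DEX against starved and EGF against DEX in each line, the difference of the EGF and of the DEX effect between the lines, and the starved lines against each other. Also fixed before the data were examined were 23 gene lists, the rule for the genes named and the alternatives, except those named as later additions. The mitochondrially encoded list had 0 measured members in the table, which left 22 lists.

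Lists were tested with fry of limma, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Its p-values were adjusted over the 22 lists of a comparison. Members called were counted over all genes tested and adjusted over the list alone. camera of limma was run with a preset correlation of 0.01 and with an estimated correlation. The genes named were, for each treatment against starved, the 12 largest rises and 8 largest falls among calls with both treated libraries on the same side of both starved libraries and a mean of at least 1 CPM in the higher group, and up to 4 members of each list with the smallest p; for the other comparisons, the 5 smallest p in each direction; and always the receptors EGFR, ERBB2, ERBB3, ERBB4, NR3C1 and NR3C2, with FKBP5, PER1, TSC22D3, FOS and EGR1. Any other gene named was chosen after its values were seen. Overlaps of calls between lines were tested with the two-sided Fisher exact test over all genes tested, also those low in 1 line. The calls of both lines came from 1 fit with a common spread per gene. The lists are therefore not fully independent, and these p-values may be too small. The EGF and DEX calls of a line share its starved libraries. For their overlaps, 100 simulations of unchanged groups against shared starved libraries were run, with noise drawn independently for each gene and library. The number expected of independent lists was computed as well.

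The recovered reads were also tested with the edgeR quasi-likelihood test (TMM and RLE scaling) and with DESeq2. Other alternatives were a fit of 1 line alone, no filter and a stricter filter, pseudocounts of 0.5 and 5, a minimum change of 1.5-fold, the replicate number as a block, and leaving out each library in turn; a group left with 1 library is then assumed to vary like the other groups. Alternatives added after seeing the data were edgeR with TMM, limma without a variance trend, a filter on group means, leaving out genes whose level in the line compared was under 1% of the level in the other line, removing from each library the trend of its log2 values with GC content and transcript length within its line (96.5% of the tested genes had both values), fits without the MCF7 DEX libraries, and the overlaps between lines without each library in turn. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

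The fits were tested on simulated data for EGF against starved in MCF7 with 50 genes changed at each fold, over 16035 genes. limma recovered 60% of 1.5-fold, 78% of 2-fold, 96% of 4-fold and 98% of 8-fold changes, and 26 of its 192 calls were false, of which 19 had levels under 10 in MCF7. This share of false calls was above the threshold of 0.05. edgeR recovered 70%, 90%, 98% and 100% with 14 false calls among 193, and DESeq2 68%, 82%, 96% and 98% with 2 false calls among 174. In the same comparison, with 16142 genes, a list of 20 raised genes gave a fry p of 6.11e-11, and 4 of 50 unchanged lists had a fry p under 0.05. Removing a simulated GC trend from DEX against starved in MCF7 (16142 genes) took the calls from 4781 to 0. These data held no DEX effect, so whether the removal keeps true changes was not tested. A share of IMR90 RNA simulated at 0.04% in the MCF7 DEX libraries was recovered as 0.0405% on average over 190 genes in 20 simulations.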

Results

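Gene expression was measured in MCF7, a breast cancer line of epithelial type that depends on the oestrogen receptor, and in IMR90, a lung fibroblast line. Cells kept overnight without serum were sampled as they were (starved) or 60 min after epidermal growth factor (EGF), the ligand of the receptor EGFR, or after dexamethasone (DEX), a synthetic agonist of the glucocorticoid receptor NR3C1. The series asks how growth factor and steroid hormone signals bear on each other, but none of the 12 libraries combined the 2 treatments. No library given vehicle for 60 min is listed in the labels. Changes against starved therefore cannot be told from effects of handling, vehicle or the added time. Each of the 6 groups held 2 libraries (n = 2 for every mean below, given as normalised read count ± SD). The MCF7 libraries held 23.5 and 22 M reads (starved), 23.5 and 21.3 M (EGF) and 18.6 and 18.5 M (DEX). The IMR90 libraries held 20.3 and 21 M (starved), 19.2 and 19.9 M (EGF) and 20.5 and 21.1 M (DEX). The 2 libraries of a group differed by more than counting error in every group, with a chi-square per gene from 1.57 (IMR90 EGF) to 9.32 (MCF7 starved). Changes are log2 fold changes ± SE from limma unless another tool is named.

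The starved lines were compared to show what each brought to the treatments. EGFR was far higher in IMR90 (2780 ± 175 against 31.2 ± 2.26 in MCF7; 6.43 ± 0.11, adjusted p = 1.01e-13). NR3C1 was higher in IMR90 as well (1681 ± 36.7 against 233.6 ± 35.5; 2.85 ± 0.09). ERBB3 and ERBB4, receptors of the same family as EGFR, were higher in MCF7 (5120 ± 55.5 and 331.5 ± 66.1 against 24.8 ± 2.81 and 1.70 ± 0.823), while ERBB2 differed little (0.20 ± 0.05, adjusted p = 0.00317). Markers of cell type separated the lines. The 13 tested epithelial markers were lower in IMR90, such as the keratin KRT8 (375.2 ± 45.3 against 164100 ± 8430; −8.77 ± 0.07) and the adhesion protein CDH1 (7.31 ± 2.28 against 22800 ± 226). The 15 tested fibroblast markers were higher, such as the collagen COL1A1 (370100 ± 10500 against 566.2 ± 12; 9.35 ± 0.04).

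Other groups of genes separated the starved lines too. Of the oestrogen receptor targets, 14 of 16 were lower in IMR90, as were 14 of 15 G1/S and 12 of 12 G2/M cell cycle genes, 9 of 10 heat shock genes, 9 of 11 steroid receptors and chaperones and 32 of 42 replication-dependent histones. Targets of SRF and the cytoskeleton were higher in IMR90 in 14 of 14 cases. Higher in IMR90 were 13 of 18 feedback attenuators, 14 of 21 glucocorticoid-induced genes, 11 of 16 NF-kappaB targets, 4 of 5 metallothioneins, 3 of 3 tested endothelial and 1 of 2 tested leukocyte markers. The rest were mixed. Higher and lower counts were 10 and 8 of 20 immediate early factors, 2 and 4 of 8 mRNA decay factors, 6 and 5 of 11 ERBB ligands and receptors, and 8 and 4 of 16 clock genes. They were 6 and 3 of 10 BMP and TGF-beta targets, 6 and 4 of 10 stress response genes, and 30 and 29 of 78 ribosomal proteins. Among the genes named in every comparison, EGR1 started higher in IMR90 (3.58 ± 0.16) and TSC22D3 and FKBP5 started lower (−3.21 ± 0.09 and −2.43 ± 0.08). In all, limma called 13897 of 16142 genes, 6903 higher and 6994 lower in IMR90.

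EGF against starved in MCF7 asks which genes the growth factor moved within the hour. Immediate early transcription factors, which cells switch on without new protein synthesis, rose together. EGR1 went from 140 ± 25.4 to 1547 ± 181 (11-fold; 3.46 ± 0.16, adjusted p = 9.24e-07) and EGR3 from 99.0 ± 16.2 to 1080 ± 50.4 (3.44 ± 0.24). FOSB went from 29.5 ± 0.0606 to 283.2 ± 9.72 (3.22 ± 0.37) and FOSL1 from 55.0 ± 3.65 to 193.5 ± 6.18 (1.80 ± 0.08). EGR2 and EGR4 had 1 to 3 reads per starved library and reached 72.1 ± 10.5 and 36.3 ± 2.34. The nuclear receptor NR4A1 rose 5.12-fold (2.36 ± 0.23), MAFF by 1.70 ± 0.16 and NAB2, a repressor that binds EGR proteins, by 1.42 ± 0.11. ATF3 rose by 1.29 ± 0.19 but lost its call without MCF7_EGF replicate 2 (adjusted p = 0.098). Of the 20 immediate early factors, 11 rose over all genes tested and 15 when adjusted over the list alone (fry adjusted p = 0.00031, and adjusted p = 0.015 with an estimated correlation). FOS itself was not called (92.3 ± 13.5 against 51.4 ± 25.2, adjusted p = 0.424).

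**Figure D1:**
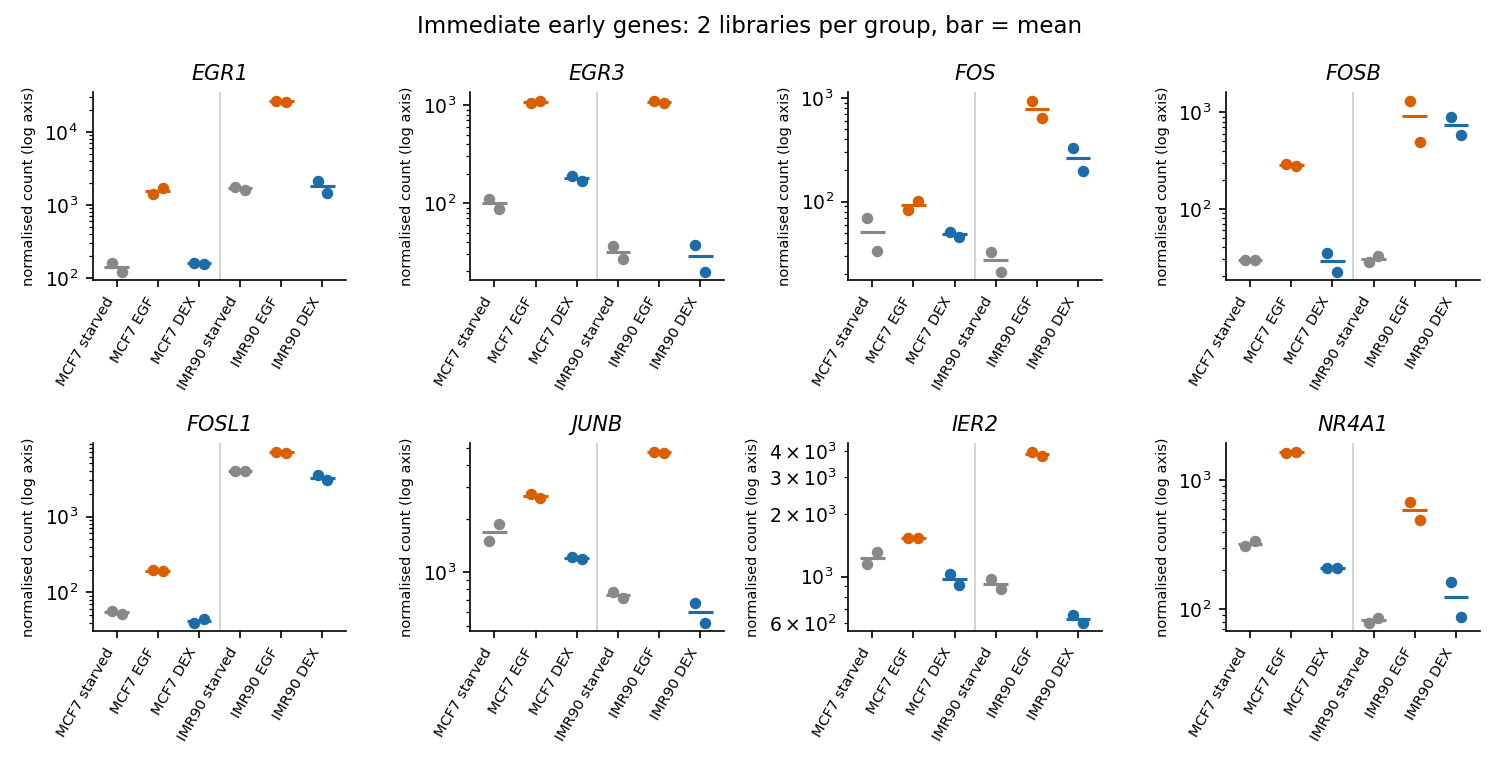
Normalised read counts (log axis) of 8 immediate early genes in the 12 libraries; points are libraries and bars are means of the 2 libraries of a group. EGR1 reached 1547 in MCF7 and 26340 in IMR90 with EGF, while FOS reached 92.3 and 790.8.

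Feedback attenuators of ERK and receptor signalling rose with EGF in MCF7 in 7 of 18 cases (9 adjusted over the list alone; fry adjusted p = 0.000398, and adjusted p = 0.0179 with an estimated correlation). They included SPRY4, an inhibitor of the RAS to ERK pathway (68.4 ± 0.254 against 16.4 ± 2.29), the phosphatase DUSP10 (0.82 ± 0.09), PHLDA1 (0.80 ± 0.06) and ERRFI1, a direct inhibitor of EGFR (0.57 ± 0.06). SRF and cytoskeleton targets rose in 5 of 14 cases (7 adjusted over the list alone; fry adjusted p = 0.00142, and adjusted p = 0.0372 with an estimated correlation). Among them, the matricellular gene CTGF went from 9.50 ± 4.17 to 120.3 ± 1.57 (3.59 ± 0.21), CYR61 rose by 1.09 ± 0.11, and SRF and VCL by 0.51 ± 0.05 and 0.51 ± 0.04. The corepressor NRIP1 was the called member of the 16 oestrogen receptor targets (0.96 ± 0.06; 2 adjusted over the list alone). That list passed fry (adjusted p = 0.047), as did the 10 BMP and TGF-beta targets (adjusted p = 0.047), and both gave an adjusted p = 0.143 with an estimated correlation. Of the BMP and TGF-beta targets, ID1 (0.89 ± 0.15) and TGFB2 (0.98 ± 0.18) were called, or 4 up and 1 down adjusted over the list alone. ID1 lost its call without any 1 of the 4 compared libraries (adjusted p up to 0.159), and TGFB2 without MCF7_starved replicate 2 or MCF7_EGF replicate 1 (adjusted p up to 0.195).

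Among mRNA decay factors, BTG1 rose (0.36 ± 0.06) and BTG2 and TOB2 fell (−0.41 ± 0.08 and −0.38 ± 0.07) (3 higher and 2 lower adjusted over the list alone), and the list did not pass (fry adjusted p = 0.247). All 3 lost their calls without MCF7_starved replicate 2 or MCF7_EGF replicate 1, and BTG2 and TOB2 also without MCF7_EGF replicate 2 (adjusted p up to 0.246); TOB2 lost its call with GC and length trends removed (−0.36 ± 0.08, adjusted p = 0.068). The 8 largest falls, in DYRK3, PLEKHF1, RAB3A, HFE, PITX2, ZNF697, GATA2 and XKR8, ran from −1.08 to −0.55. Each lost its call without 2 or more of the 4 compared libraries (adjusted p up to 0.24). This held for PITX2 without any 1 of them, for HFE without MCF7_EGF replicate 1 or either starved library and for GATA2 without MCF7_starved replicate 1 or either EGF library. It held for DYRK3, RAB3A and XKR8 without MCF7_starved replicate 2 or either EGF library and for PLEKHF1 and ZNF697 without replicate 2 of either group. Of the 17 lists that did not pass, the lowest fry adjusted p was 0.0585 (ERBB ligands and receptors). Their called members, with the count adjusted over the list alone, were ERRFI1 of the glucocorticoid-induced genes (4; fry adjusted p = 0.101) and BHLHE40 of the clock genes (0.64 ± 0.09; 1 higher and 1 lower; fry adjusted p = 0.75). Also called were LIF of the NF-kappaB targets (0.81 ± 0.11; 3; fry adjusted p = 0.213) and CCND1 of the G1/S genes (0.34 ± 0.05; 1; fry adjusted p = 0.444). HSPA1B of the heat shock genes (−0.34 ± 0.07; 3 lower; fry adjusted p = 0.11) and SESN2 of the stress response genes (−0.40 ± 0.07; 2 higher and 2 lower; fry adjusted p = 0.129) fell. BHLHE40 lost its call without MCF7_EGF replicate 1 (adjusted p = 0.0761), LIF without MCF7_EGF replicate 2 (adjusted p = 0.0534) and CCND1 without either (adjusted p up to 0.0816). HSPA1B and SESN2 lost theirs without MCF7_starved replicate 2 or either EGF library (adjusted p up to 0.246 and 0.136), and HSPA1B also with GC and length trends removed (−0.33 ± 0.08, adjusted p = 0.0896). HSPA1B shares reads with its near-identical copy HSPA1A, so its value is uncertain. Among fibroblast markers, FBN1 and PDGFRB were called higher and PDGFRA lower by limma, at levels up to 30.96 ± 1.41, and edgeR called 0 of the 15; FBN1 and PDGFRA lost their calls without MCF7_starved replicate 1 or either EGF library (adjusted p up to 0.26). The median of this list was negative and its mean positive (fry adjusted p = 0.81). In the other 9 lists (ERBB, metallothionein, steroid receptor and chaperone, G2/M, epithelial, endothelial, leukocyte, ribosomal and histone lists) limma called 0 of 177 members, with 3 at an unadjusted p under 0.05, 1 adjusted over its list alone, 2 called by edgeR and 2 by DESeq2.

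The limma test called 123 genes with EGF in MCF7, 89 higher and 34 lower, of which 53 and 11 changed at least 1.5-fold. The edgeR test called 129 higher and 131 lower and DESeq2 96 and 35. The count rose by more than 1.5 times without MCF7_starved replicate 1. It fell by more than 1.5 times without any 1 of the EGF libraries of either line. The lower calls fell as far without MCF7_starved replicate 2 too, and without any 1 of the IMR90 starved and DEX libraries, which were not compared here. Many of the 40 named calls were lost without at least 1 of the 4 compared libraries, and the other libraries were not left out for named calls.

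EGF in IMR90 asks the same of the fibroblasts, and immediate early genes again led. EGR1 went from 1676 ± 129 to 26340 ± 684 (15.7-fold; 3.98 ± 0.16, adjusted p = 1.32e-07) and EGR3 from 31.6 ± 6.86 to 1078 ± 42.8 (5.06 ± 0.24). FOS went from 27.1 ± 8.39 to 790.8 ± 217 (4.82 ± 0.35) and FOSB from 30.4 ± 2.73 to 903.5 ± 588 (4.68 ± 0.37). EGR2 (3.87 ± 0.37), NR4A1 (2.81 ± 0.23), JUNB (2.67 ± 0.11), ATF3 (2.30 ± 0.19), KLF2 (2.12 ± 0.11) and IER2 (2.07 ± 0.08) rose as well. Of the 20 immediate early factors, 18 rose over all genes tested and 20 adjusted over the list alone (fry adjusted p = 4.84e-06, and adjusted p = 0.000722 with an estimated correlation). Feedback attenuators rose in 9 of 18 cases (13 adjusted over the list alone; fry adjusted p = 2.22e-05, and adjusted p = 0.00148 with an estimated correlation). Among them were the ERK and stress kinase phosphatases DUSP2 (110.1 ± 2.49 against 18.6 ± 0.515), DUSP1 (1.84 ± 0.09) and DUSP5 (1.41 ± 0.09) and IER3 (1.44 ± 0.12). Factors of mRNA decay, which shorten the life of early transcripts, rose in 6 of 8 cases (7 adjusted over the list alone; fry adjusted p = 4.84e-06, and adjusted p = 0.000722 with an estimated correlation). ZFP36 rose by 1.92 ± 0.09, ZC3H12A by 0.91 ± 0.07, ZFP36L1 by 0.57 ± 0.04 and TOB1 by 0.37 ± 0.05.

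Of the other lists, 4 passed with EGF in IMR90. Of the 16 NF-kappaB and inflammatory targets, 3 rose (6 adjusted over the list alone; fry adjusted p = 0.000321, and adjusted p = 0.00554 with an estimated correlation). NFKBIZ rose by 1.58 ± 0.10, the cytokine LIF by 1.42 ± 0.11, and PTGS2, the inducible cyclooxygenase, from 15.9 ± 9.81 to 142.4 ± 15.2. PTGS2 was not called by DESeq2 (adjusted p = 0.0991) and lost its limma call without IMR90_starved replicate 2 or either IMR90_EGF library (adjusted p up to 0.0886). Of the 21 canonical glucocorticoid-induced genes, 4 rose with EGF (9 higher and 2 lower adjusted over the list alone; fry adjusted p = 0.000321, and adjusted p = 0.0113 with an estimated correlation). They were DUSP1, TSC22D3, a glucocorticoid-induced leucine zipper (1.26 ± 0.09), the clock gene PER1 (0.94 ± 0.07) and ERRFI1 (0.65 ± 0.06), of which DUSP1 and ERRFI1 are feedback attenuators as well. PPP1R15A, which directs a phosphatase to eIF2alpha, was the called member of the 10 stress response genes (0.58 ± 0.06; list median 0.07; 4 adjusted over the list alone; fry adjusted p = 0.000214, and adjusted p = 0.0133 with an estimated correlation). The 16 clock genes, with PER1 and BHLHE40 (0.81 ± 0.09) called, 3 adjusted over the list alone and a median of 0, passed fry at an adjusted p = 0.0389 (adjusted p = 0.158 with an estimated correlation, and 0.0556 by fry with GC and length trends removed).

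Outside the lists that passed, HBEGF, a ligand of EGFR, rose by 1.07 ± 0.17 and CYR61 by 0.76 ± 0.11. HBEGF lost its call without IMR90_EGF replicate 1 or either starved library (adjusted p up to 0.112) and CYR61 without IMR90_starved replicate 1 or either EGF library (adjusted p up to 0.1). Each was the called member of its list (ERBB ligands and receptors, 1 adjusted over the list alone, fry adjusted p = 0.683; SRF and cytoskeleton targets, 2 adjusted over the list alone, fry adjusted p = 0.517). The long non-coding RNA NEAT1 fell by 0.42 ± 0.05 (11680 ± 442 to 8756 ± 414). The other 4 of the 5 largest falls (GAN, CLSPN, FANCG and NDC1, −0.77 to −0.31) were not called by edgeR. Each lost its call without IMR90_starved replicate 1 or IMR90_EGF replicate 1, CLSPN, FANCG and NDC1 also without IMR90_EGF replicate 2, and CLSPN and FANCG also without IMR90_starved replicate 2 (adjusted p up to 0.206). In the remaining 13 lists (metallothionein, steroid receptor and chaperone, oestrogen target, BMP and TGF-beta, G1/S, G2/M, heat shock, epithelial, fibroblast, endothelial, leukocyte, ribosomal and histone lists) limma called 0 of 231 members, with 23 at an unadjusted p under 0.05 and 2 called by each of edgeR and DESeq2. Adjusted over each list alone, 4 were higher and 6 lower, 4 of the 6 among the 12 G2/M genes (fry adjusted p = 0.159, and adjusted p = 3.04e-07 with the preset and 0.218 with an estimated correlation). The heat shock and histone lists had medians and means of opposite sign. With limma 107 genes were called, 92 higher and 15 lower (67 and 11 at least 1.5-fold). The lower calls numbered 6 to 31 when 1 of the 12 libraries was left out, with 31 without IMR90_EGF replicate 2 and 6 without MCF7_EGF replicate 1. The edgeR test called 129 and 7, and 1 of the 15 lower calls was also made by edgeR. Most but not all of the 34 named calls passed without each of the 4 compared libraries in turn. The other libraries were not left out for named calls.

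**Figure D2:**
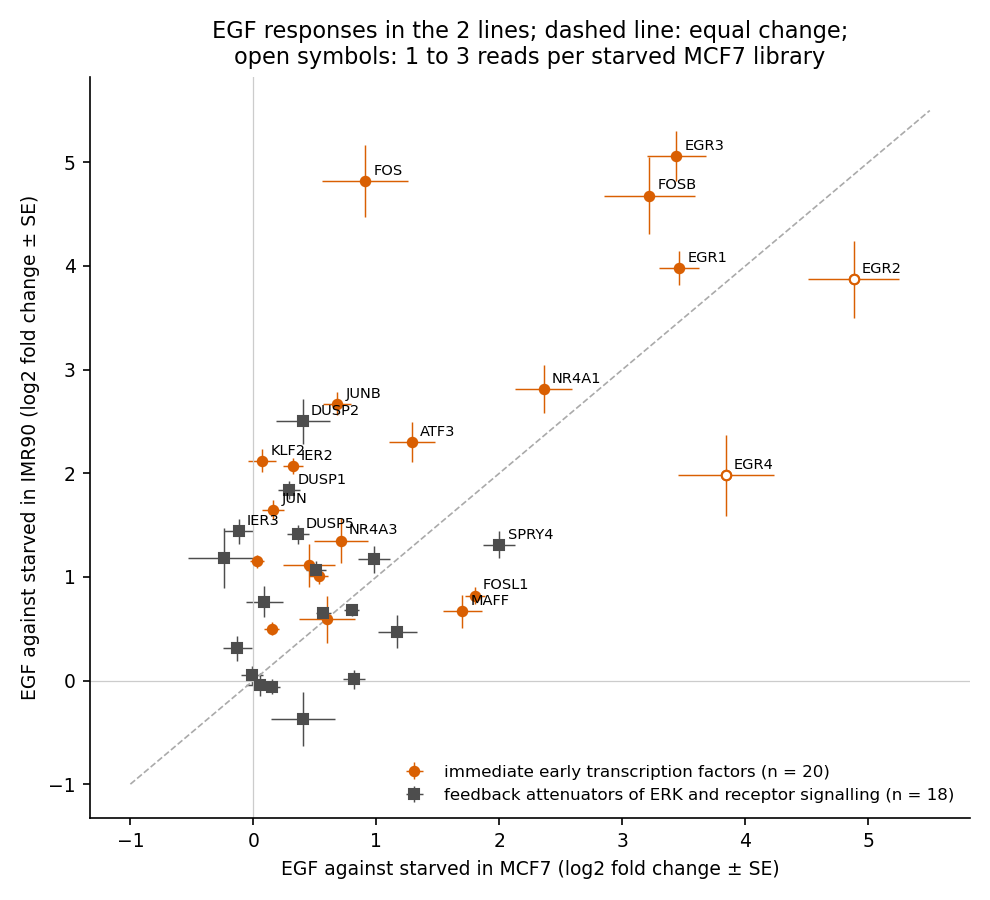
EGF effect (log2 fold change ± SE, n = 2 libraries per group) in MCF7 (horizontal axis) and IMR90 (vertical axis) for the 20 immediate early factors and 18 feedback attenuators tested, where the dashed line marks equal change and open symbols mark genes with 1 to 3 reads per starved MCF7 library. FOS lies at 0.91 in MCF7 and 4.82 in IMR90, while EGR1 lies at 3.46 and 3.98.

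The EGF effect was then compared between the lines, as the difference of the IMR90 and MCF7 changes. FOS rose more in IMR90 by 3.91 ± 0.49 (adjusted p = 0.00374), and so did KLF2 (2.05 ± 0.15), IER2 (1.75 ± 0.11), the mRNA decay factor ZFP36 (1.68 ± 0.13), the small GTPase gene RHOB (1.41 ± 0.07) and KLF6 (1.12 ± 0.09). TSC22D3 and PER1 also moved more in IMR90 (1.46 ± 0.13 and 0.88 ± 0.10, adjusted p = 0.000207 and 0.00261); with EGF in MCF7 they were at 1909 ± 83.9 and 329.1 ± 4.89 against 2187 ± 94.3 and 316.8 ± 2.43 starved. The effect was larger in MCF7 for CTGF (−2.97 ± 0.30), FOSL1 (−0.97 ± 0.11), NRIP1 (−0.97 ± 0.09), SGK223 (−0.76 ± 0.09) and VCL (−0.60 ± 0.06). EGR1 did not differ by this test (0.51 ± 0.22, adjusted p = 0.642). Differences were called in 54 genes, 36 higher and 18 lower in IMR90; edgeR called 76 and 38, and DESeq2 51 and 34. The count was 119 without MCF7_starved replicate 1 (53 higher and 66 lower), and 32 to 35 without MCF7_EGF replicate 1 or 2 or IMR90_EGF replicate 1 or 2.

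The lines shared 23 of the genes called higher with EGF (89 in MCF7 and 92 in IMR90), against 0.507 expected of independent lists (Fisher exact adjusted p = 4.36e-32 over 4 overlaps). They included EGR1, EGR2, EGR3, EGR4, FOSB, FOSL1, NR4A1, ATF3, SPRY4, PHLDA1 and ERRFI1. Both lists came from 1 fit with a common spread per gene, so the p-value of this overlap may be too small. Of genes called lower, 0 were shared by limma, edgeR or DESeq2, with 31 lower in both lines at an unadjusted p under 0.05. BTG2, which was lower in MCF7, was higher in IMR90 (difference 0.91 ± 0.11, adjusted p = 0.00261).

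DEX against starved in MCF7 asks which genes the glucocorticoid moved in the epithelial line. BCL6, a transcriptional repressor, went from 225 ± 23.4 to 719.6 ± 22.2 (3.2-fold; 1.68 ± 0.08, adjusted p = 4.9e-07) and PER1 from 316.8 ± 2.43 to 838.3 ± 10.4 (2.64-fold; 1.40 ± 0.07, adjusted p = 1.53e-06). ERRFI1 rose by 0.41 ± 0.06 and KLF9 by 0.59 ± 0.14, but KLF9 lost its call without any 1 of the 4 compared libraries (adjusted p up to 0.186) and with GC and length trends removed (0.59 ± 0.13, adjusted p = 0.0607). These were the 4 of 21 canonical glucocorticoid-induced genes that rose (5 adjusted over the list alone; fry adjusted p = 0.00186, and adjusted p = 0.216 with an estimated correlation). FKBP5 and TSC22D3, further members, stayed at 984.9 ± 21.6 and 2012 ± 10.7 against 988.7 ± 6.54 and 2187 ± 94.3 and were not called (adjusted p = 1 and 0.547). Of the oestrogen receptor targets, NRIP1 (0.65 ± 0.06) and SIAH2 (0.32 ± 0.07) rose, 2 of 16 (2 adjusted over the list alone; fry adjusted p = 0.176); SIAH2 lost its call without MCF7_starved replicate 2 or either DEX library (adjusted p up to 0.227).

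**Figure D3:**
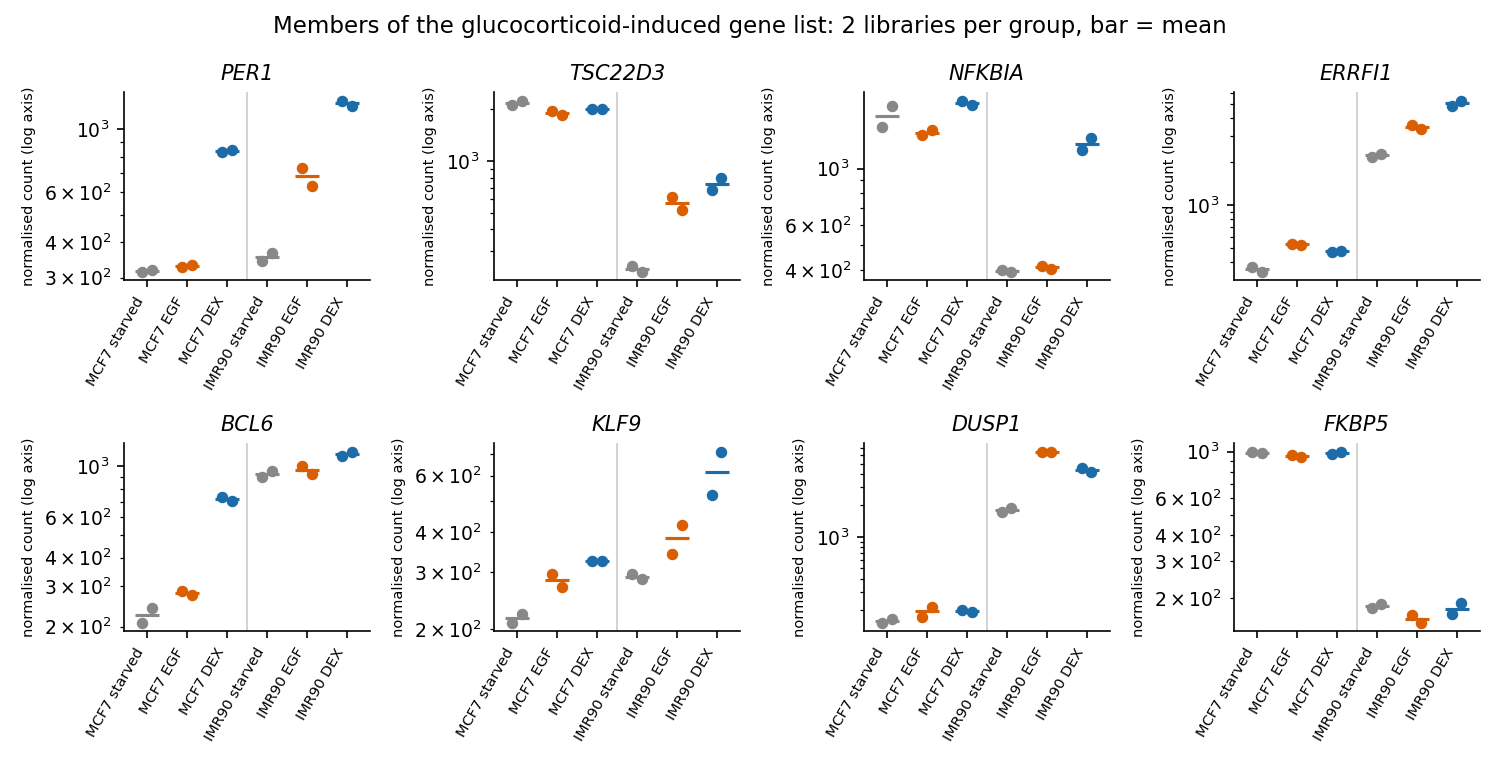
Normalised read counts (log axis) of 8 members of the glucocorticoid-induced gene list in the 12 libraries; points are libraries and bars are means of the 2 libraries of a group. PER1 reached 838.3 with DEX in MCF7 and 1232 in IMR90, while FKBP5 stayed at 984.9 and 177.7.

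Among falls with DEX in MCF7, IER5L went from 1708 ± 1.44 to 909.2 ± 19.4 (−0.91 ± 0.07), the NF-kappaB regulator BCL3 from 2569 ± 8.63 to 1491 ± 27.1 (−0.78 ± 0.08), TOB2 by −0.68 ± 0.07 and SESN2 by −0.57 ± 0.07. The immediate early factor JUN fell from 629.6 ± 93.9 to 397.2 ± 17.6 (−0.66 ± 0.09). JUN was among 5 of 20 immediate early factors that fell, with FOSL1, IER2, IER5 and, at an adjusted p = 0.0499, JUNB (3 higher and 7 lower adjusted over the list alone), and the list did not pass (fry adjusted p = 0.178). FOSL1, IER2 and IER5 (−0.38 ± 0.08, −0.34 ± 0.08 and −0.32 ± 0.06) each lost the call without either DEX library, FOSL1 also without MCF7_starved replicate 1 and IER2 and IER5 also without replicate 2 (adjusted p up to 0.269). With GC and length trends removed they were −0.34 ± 0.08, −0.24 ± 0.09 and −0.30 ± 0.07 (adjusted p = 0.0566, 0.239 and 0.0551), and the list median stayed at −0.12. Of the mRNA decay factors, BTG1 rose and BTG2 and TOB2 fell (fry adjusted p = 0.00186, and adjusted p = 0.125 with an estimated correlation; 1 higher and 4 lower adjusted over the list alone). BTG1 (0.26 ± 0.06) lost its call without any 1 of the 4 libraries (adjusted p up to 0.218) and with GC and length trends removed (0.20 ± 0.06, adjusted p = 0.109), and BTG2 (−0.51 ± 0.08) without MCF7_DEX replicate 2 (adjusted p = 0.0626). SESN2 was the called member of the 10 stress response genes (2 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.0061, and adjusted p = 0.485 with an estimated correlation). The list had a fry adjusted p = 0.158 once GC and length trends were removed. Other falls among the 8 largest were NFKBID, FUT4, FAXDC2, NPAS1, LOC103171574 and the ribosomal RNA repeat RNA45S5, whose copies share reads. They ran from −1.08 to −0.78 together with IER5L and BCL3. Each of these 6 lost its call without 1 or more of the 4 libraries (adjusted p up to 0.186). NFKBID did so without MCF7_DEX replicate 1 (adjusted p = 0.0556), FUT4 without MCF7_starved replicate 1 or MCF7_DEX replicate 2. RNA45S5 and LOC103171574 did so without MCF7_starved replicate 1 or either DEX library, and FAXDC2 and NPAS1 without any 1 of the 4. NPAS1 went from −0.98 ± 0.22 to −0.84 ± 0.23 with GC and length trends removed (adjusted p = 0.109). Rises outside the lists were SGPP2 (1.22 ± 0.26), which lost its call without MCF7_starved replicate 2 or either DEX library (adjusted p up to 0.144), and ZNF487 (1.09 ± 0.24). ZNF487 lost its call without any 1 of the 4 (adjusted p up to 0.163) and with GC and length trends removed (1.03 ± 0.24, adjusted p = 0.0633).

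Transcripts typical of fibroblasts were also higher in the MCF7 DEX libraries. COL1A2 had 1 and 0 reads in the starved libraries and a level of 91.4 ± 3.38 with DEX, against 224100 ± 13000 in IMR90 with DEX. SPARC was at 41.0 ± 2.73 against 2.78 ± 0.463 starved, VIM at 45.0 ± 4.18 against 6.33 ± 3.16, DCN at 11.7 ± 5.54 against 0.409 ± 0.579, and COL6A3 at 76.7 ± 2.14 against 35.5 ± 0.72. Of the 15 fibroblast markers, 9 rose (11 adjusted over the list alone; fry adjusted p = 1.79e-05, and adjusted p = 0.00369 with an estimated correlation). FSTL1 (1.33 ± 0.11), SPON2 (1.14 ± 0.15), LOX (1.08 ± 0.21) and SERPINE1 (1.09 ± 0.10), at 18.1 to 24.9, were higher too, LOX losing its call without MCF7_starved replicate 1 or either DEX library (adjusted p up to 0.169). A set of 190 genes restricted to IMR90 had a mean of at least 1000 there and under 0.2% of it in the MCF7 starved and EGF libraries. Over these genes the DEX excess amounted to 0.0436% and 0.0444% of the IMR90 level in the 2 DEX libraries. Of the 190, 73 were called higher and 1 lower, in a set chosen as low in the starved and EGF libraries only. Of the 218 genes called higher with DEX, 90 lay under 1% of their IMR90 level.

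**Figure D4:**
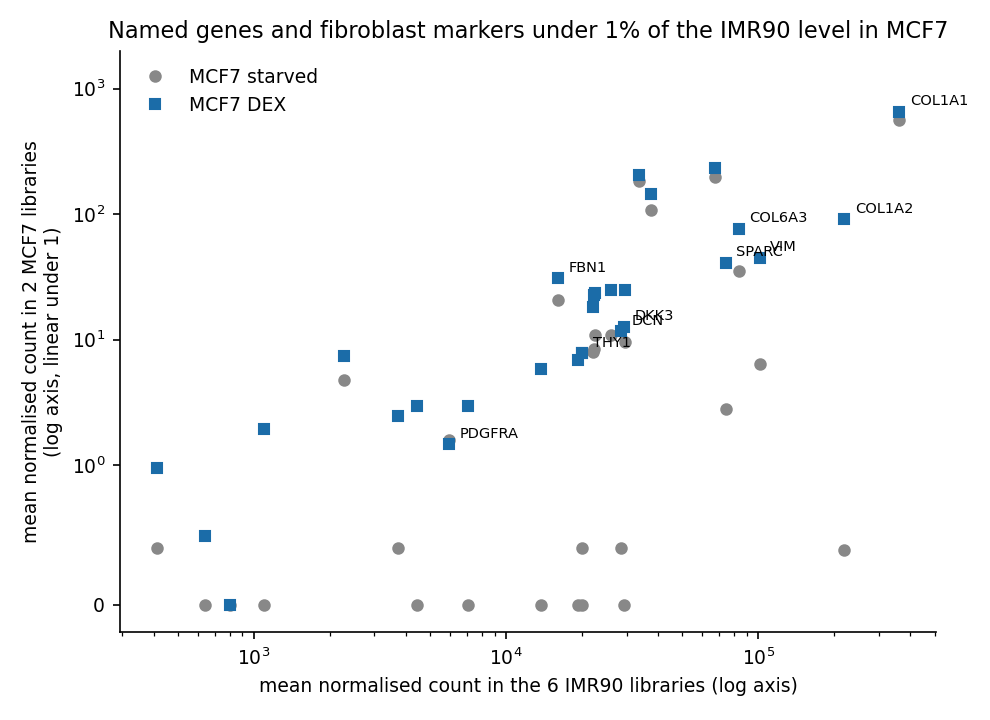
Mean normalised read counts in the 2 starved and the 2 DEX libraries of MCF7 (vertical axis, log above 1 and linear under it) against the mean of the 6 IMR90 libraries (log axis), for the 29 named genes and fibroblast markers under 1% of their IMR90 level in MCF7. COL1A2 lies at 0.389 in starved and 91.4 in DEX libraries.

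The cytoskeleton targets CTGF (24.9 ± 6.2 against 9.50 ± 4.17), TAGLN and CNN1 were higher in the MCF7 DEX libraries, while SRF was lower (−0.33 ± 0.05). These were 3 higher and 1 lower of 14 (6 and 1 adjusted over the list alone, fry adjusted p = 0.176). The 3 higher genes are abundant in IMR90 and lay under 1% of that level in MCF7. TAGLN was at 144 against 107 starved and CNN1 at 2.44 against 0.409. The starved and EGF mean plus the excess share of IMR90 given above would be 129 and 1.84. Their rises therefore cannot be told from that share. For CTGF, which rose with EGF, this sum is no guide. CTGF lost its call without MCF7_DEX replicate 1 (adjusted p = 0.0851), and TAGLN, CNN1 and SRF theirs without either DEX library (adjusted p up to 0.134). Cytoplasmic ribosomal proteins rose in 11 of 78 cases (36 adjusted over the list alone; fry adjusted p = 0.147). The rise was 0.30 ± 0.05 for RPS17, 0.28 ± 0.06 for RPS27, 0.24 ± 0.05 for RPL39 and 0.23 ± 0.05 for RPS3A. These lost their calls without either DEX library, and all but RPS17 also without MCF7_starved replicate 1 (adjusted p up to 0.16). DUSP6 rose and DUSP5 fell among 18 feedback attenuators, with ERRFI1 as the other call (4 higher and 4 lower adjusted over the list alone; fry adjusted p = 0.999). Of 10 heat shock genes, DNAJB1, HSPA1A and HSPA1B fell and HSPD1 rose (2 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.176). Of the BMP and TGF-beta targets, SERPINE1 rose and ID2 fell (fry adjusted p = 0.883). DUSP5, DUSP6, the 4 heat shock genes and ID2 lost their calls without either DEX library, and DUSP6 and HSPD1 also without MCF7_starved replicate 1 and ID2 without replicate 2 (adjusted p up to 0.172). MT1E was called among 5 metallothioneins at 1.95 ± 1.38 against 0 (fry adjusted p = 0.147) and lost its call without MCF7_starved replicate 1 or MCF7_DEX replicate 1 (adjusted p up to 0.0783); PER1 was the called clock gene of 16 (fry adjusted p = 0.687). In the other 9 lists (ERBB, NF-kappaB, steroid receptor and chaperone, G1/S, G2/M, epithelial, endothelial, leukocyte and histone lists) limma called 0 of 125 members, with 7 at an unadjusted p under 0.05, 1 adjusted over its list alone, 6 called by edgeR and 4 by DESeq2. In 6 lists (feedback, NF-kappaB, clock, BMP and TGF-beta, G1/S and histone lists) the median, the mean and the test differed in sign.

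The slope of log2 value on GC fraction was −0.317 and −0.511 in the MCF7 DEX libraries, 0.253 and 0.03 in the EGF libraries and 0.68 and −0.134 in the starved libraries. With GC and length trends removed, 2 ribosomal calls were left and RPS3A went from 0.23 ± 0.05 to 0.11 ± 0.03, RPS27 from 0.28 ± 0.06 to 0.15 ± 0.04 and RPL39 from 0.24 ± 0.05 to 0.18 ± 0.04 (adjusted p = 0.121, 0.114 and 0.0608). HSPA1B went from −0.38 ± 0.07 to −0.32 ± 0.08, HSPA1A from −0.35 ± 0.06 to −0.28 ± 0.07, and HSPD1 from 0.18 ± 0.04 to 0.12 ± 0.04 (adjusted p = 0.0735, 0.0969 and 0.148). DUSP5 went from −0.45 ± 0.09 to −0.40 ± 0.10 and SRF from −0.33 ± 0.05 to −0.21 ± 0.06 (adjusted p = 0.0662 and 0.121). RNA45S5 took 1.268% and 1.497% of reads in the DEX libraries against 1.936% to 3.244% in the other 4 MCF7 libraries. The limma test called 482 genes, 218 higher and 264 lower, of which 70.7% changed less than 1.5-fold. The edgeR test called 325 and 602, and DESeq2 244 and 366. The count was 196 with GC and length trends removed, 126 higher and 70 lower (179 of them among the 482), and 86 when genes under 1% of the IMR90 level were left out as well. It was 831 without MCF7_starved replicate 2, 115 without MCF7_DEX replicate 1 (71 higher and 44 lower) and 124 without MCF7_DEX replicate 2 (79 and 45), so the larger side depended on the fit. Most of the 49 named calls were lost without at least 1 of the 4 compared libraries. The other libraries were not left out for named calls.

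DEX against starved in IMR90 asks the same of the fibroblasts, and several known glucocorticoid targets rose. PER1 went from 354.6 ± 16.1 to 1232 ± 41.7 (3.47-fold; 1.79 ± 0.07, adjusted p = 5.83e-07), TSC22D3 from 235.2 ± 12.3 to 738.6 ± 80.8 (1.64 ± 0.09) and NFKBIA, the inhibitor of NF-kappaB, from 397.6 ± 3.64 to 1251 ± 92.1 (1.65 ± 0.08). The kinase gene SGK1 rose by 1.38 ± 0.13, DUSP1 by 1.26 ± 0.09, and ERRFI1 rose from 2218 ± 85.1 to 5116 ± 292. Of the 21 canonical glucocorticoid-induced genes, 9 rose (11 adjusted over the list alone; fry adjusted p = 4.39e-05, and adjusted p = 0.00355 with an estimated correlation), while FKBP5 was not called (177.7 ± 15.5 against 182.7 ± 5.2, adjusted p = 1). GADD45B (1.21 ± 0.08) and KLF6 (11180 ± 214 against 4869 ± 36.9) rose too, as did C10orf10 (1.48 ± 0.22) and PRDM1 (1.44 ± 0.22), which lost their calls without any 1 of the 4 compared libraries (adjusted p up to 0.124).

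Immediate early factors split with DEX in IMR90. FOS went from 27.1 ± 8.39 to 263.2 ± 92.8 (3.22 ± 0.35), FOSB from 30.4 ± 2.73 to 734.7 ± 220 (4.52 ± 0.37), and KLF6 and ATF3 rose. IER2 fell from 920.8 ± 71.4 to 629.5 ± 38.1 (−0.55 ± 0.08) and EGR1 was not called (1805 ± 488 against 1676 ± 129, adjusted p = 1). In all 4 of 20 rose and 1 fell (4 and 3 adjusted over the list alone; fry adjusted p = 0.116). Feedback attenuators rose in 4 of 18 cases (DUSP1, ERRFI1, DUSP5 by 1.04 ± 0.09 and TRIB1 by 0.64 ± 0.08) and IER3 fell (−0.71 ± 0.12), 5 and 1 adjusted over the list alone (fry adjusted p = 0.00664, and adjusted p = 0.239 with an estimated correlation). Of the 8 mRNA decay factors ZFP36 (0.99 ± 0.09) and ZFP36L2 (0.41 ± 0.06) rose, with 2 higher and 2 lower adjusted over the list alone (fry adjusted p = 0.0326, and adjusted p = 0.279 with an estimated correlation). PER1 was the called clock gene of 16 (2 adjusted over the list alone; fry adjusted p = 0.0437, adjusted p = 0.468 with an estimated correlation, and 0.0557 by fry with GC and length trends removed). The NF-kappaB targets held NFKBIA as a rise and LIF as a fall (−0.67 ± 0.11, and −0.65 ± 0.12 with an adjusted p = 0.0542 once GC and length trends were removed). There were 3 higher and 1 lower adjusted over the list alone (fry adjusted p = 0.0847). The stress response genes held DDIT4 as a rise (0.88 ± 0.15; 1 higher and 1 lower adjusted over the list alone; fry adjusted p = 0.26).

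The 5 largest falls with DEX in IMR90 were ATP2A3 (−0.73 ± 0.11, not called by edgeR), IER3, LIF, IER2 and PLK2 (−0.44 ± 0.06). Each lost its call without 2 or more of the 4 compared libraries (adjusted p up to 0.198), as did DDIT4, TRIB1 and ZFP36L2 (adjusted p up to 0.15). IER3 did so without any 1 of them, LIF, PLK2 and DDIT4 without IMR90_DEX replicate 2 or either starved library, and IER2 without IMR90_starved replicate 1 or IMR90_DEX replicate 2. ATP2A3 and TRIB1 did so without either DEX library, and ZFP36L2 without IMR90_starved replicate 2 or either DEX library. In the other 15 lists (ERBB, SRF and cytoskeleton, metallothionein, steroid receptor and chaperone, oestrogen target, BMP and TGF-beta, G1/S, G2/M, heat shock, epithelial, fibroblast, endothelial, leukocyte, ribosomal and histone lists) limma called 0 of 256 members, with 25 at an unadjusted p under 0.05, 4 higher and 4 lower adjusted over each list alone, and 1 called by each of edgeR and DESeq2. The SRF, NF-kappaB, stress response and fibroblast lists differed in sign between median, mean and test. With limma 43 genes were called, 35 higher and 8 lower, while edgeR called 51 and 18, and DESeq2 45 and 12. The count was 26 when the MCF7 DEX libraries were left out of the fit. There were fewer lower calls without any 1 of the MCF7 EGF and DEX libraries and more without IMR90_DEX replicate 2. Many but not all of the 22 named calls passed without each of the 4 compared libraries in turn. The other libraries were not left out for named calls.

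The DEX effect was compared between the lines in the same way. TSC22D3 (1.76 ± 0.13, adjusted p = 4.03e-05), DUSP5 (1.49 ± 0.12), NFKBIA (1.47 ± 0.11), KLF6 (1.25 ± 0.09) and ERRFI1 (0.80 ± 0.08) rose more in IMR90. FOS did as well (3.22 ± 0.49, adjusted p = 0.0118), but lost its call without either MCF7_DEX library, IMR90_starved replicate 2 or IMR90_DEX replicate 1 (adjusted p up to 0.0839). Outside the naming rule and chosen after its values were seen, BCL6 moved more in MCF7 (−1.38 ± 0.11, adjusted p = 7.95e-05). PER1 did not differ by this test (0.39 ± 0.10, adjusted p = 0.207). The 5 smallest p in the other direction were COL1A2 (−6.09 ± 0.37), DKK3 (−3.76 ± 0.13), GREM1 (−3.19 ± 0.24), SFRP1 (−2.99 ± 0.18) and IGFBP7 (−2.73 ± 0.19). Each was at least 13800 ± 350 in starved IMR90 and belonged to the fibroblast transcripts found in the MCF7 DEX libraries. The limma test called 68 differences, 29 higher and 39 lower in IMR90, edgeR 64 and 33, and DESeq2 47 and 27. The count was 39 without genes under 1% of the other line (33 higher and 6 lower) and 115 without MCF7_starved replicate 2. The lines shared 3 genes called higher with DEX, PER1, ERRFI1 and KLF9, against 0.473 expected (Fisher exact adjusted p = 0.0232). As both lists came from 1 fit with a common spread per gene, this p-value may be too small. KLF9 in MCF7 lost its call without any 1 of the 4 compared libraries (adjusted p up to 0.186) and with GC and length trends removed (adjusted p = 0.0607), where its change was 0.59 ± 0.13 against 0.59 ± 0.14 before. The overlap did not pass without MCF7_starved replicate 2, IMR90_starved replicate 1 or IMR90_starved replicate 2 (Fisher exact adjusted p = 0.0722, 0.148 and 0.107, with 3, 2 and 2 shared genes), while PER1 and ERRFI1 were shared without each library in turn. Of genes called lower, the lines shared 1, IER2, against 0.131 expected (adjusted p = 0.165), and IER2 in MCF7 lost its call without MCF7_starved replicate 2 or either DEX library (adjusted p up to 0.269). DUSP5 was called lower in MCF7 and higher in IMR90.

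EGF was set against DEX within each line. In MCF7, EGR1 (3.28 ± 0.16, adjusted p = 5.65e-07), FOSL1 (2.18 ± 0.08), NAB2 (1.98 ± 0.11), SRF (0.84 ± 0.05) and VCL (0.61 ± 0.04) were higher with EGF. PER1 (−1.35 ± 0.07) and BCL6 (−1.35 ± 0.08) were lower with EGF than with DEX, as were the fibroblast transcripts COL1A2 (0.432 ± 0.611 against 91.4 ± 3.38), VIM (−2.77 ± 0.21) and COL6A3 (−1.27 ± 0.07). In total 205 genes were called by limma, 112 higher and 93 lower with EGF; edgeR called 189 and 58, and DESeq2 148 and 50. The count was 110 without genes under 1% of the IMR90 level. It was 134 without MCF7_EGF replicate 1 (58 higher and 76 lower) and 187 with GC and length trends removed (93 and 94). In IMR90, EGR3 (5.25 ± 0.24), EGR1 (3.89 ± 0.16), JUNB (2.99 ± 0.11), IER2 (2.62 ± 0.08, adjusted p = 1.78e-08) and RHOB (1.24 ± 0.05) were higher with EGF. NFKBIA (−1.60 ± 0.08), GADD45B (−1.20 ± 0.08), PER1 (−0.86 ± 0.07), the GTPase gene ARL4A (−0.81 ± 0.09) and ERRFI1 (−0.55 ± 0.06) were lower with EGF than with DEX. In total 164 genes were called by limma, 127 higher and 37 lower with EGF; edgeR called 179 and 45, and DESeq2 146 and 34.

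Calls shared by EGF and DEX within a line were counted because both treatments were set against the same starved libraries. In IMR90, 17 genes were higher with both, among them FOS, FOSB, ATF3, DUSP1, DUSP5, ERRFI1, PER1, TSC22D3, TRIB1 and ZFP36. Unchanged groups gave 0.01 on average and at most 1 in 100 simulations, and independent lists would share 0.199. Of genes lower with both in IMR90, limma and DESeq2 found 0 and edgeR 1, with 129 at an unadjusted p under 0.05 in both. In MCF7, 23 genes were higher with both, including NRIP1 and ERRFI1 (0 in simulations and 1.2 expected). A further 20 were lower with both, including BTG2, TOB2 and SESN2 (0.01 on average and at most 1 in simulations, and 0.556 expected). Between EGF and DEX, 8 of the 23 and 1 of the 20 differed by limma. Handling shared by both treated arms was not weighed for these MCF7 genes. Without genes under 1% of the IMR90 level 15 higher genes were shared in MCF7, and with GC and length trends removed 8 lower genes. The 2 starved libraries of a line were not split between the treatments for these overlaps, so part of each excess may come from the shared controls.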

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

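In this part the tests of explanations were chosen only after the result was seen, except the removal of GC and length trends, whose prediction was written before it was run. A difference of an effect between the 2 lines, tested as an interaction, put a result here. The EGF effect differed in 36 genes toward IMR90 and 18 toward MCF7: FOS 3.91, KLF2 2.05, IER2 1.75, ZFP36 1.68, TSC22D3 1.46, RHOB 1.41, KLF6 1.12, PER1 0.88, VCL −0.6, SGK223 −0.76, FOSL1 −0.97, NRIP1 −0.97 and CTGF −2.97 (log2, IMR90 minus MCF7). The DEX effect differed in 29 genes toward IMR90 and 39 toward MCF7: FOS 3.22, TSC22D3 1.76, DUSP5 1.49, NFKBIA 1.47, KLF6 1.25, ERRFI1 0.8, IGFBP7 −2.73, SFRP1 −2.99, GREM1 −3.19, DKK3 −3.76 and COL1A2 −6.09.

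The IMR90-abundant transcripts higher in the MCF7 DEX libraries, among them COL1A2 and DKK3, were weighed as a small share of IMR90 RNA or reads against induction by DEX. If a share were the cause, the reads of 190 genes restricted to IMR90 should follow their IMR90 level with a dispersion of at most 2, and induction should leave more than 2. The dispersion was 1.22 around a share of 0.0436% in the library of replicate 1 and 1.09 around 0.0444% in that of replicate 2. The higher value, 1.22, fits a share and, as the same value read for induction, argues against induction unrelated to the IMR90 level. In simulations a share gave at most 1.23, and an equal step in a random part of the genes at least 34.4. Other forms of induction were not simulated. By the same measure MCF7_starved replicate 2 had a dispersion of 3.92. The genes were chosen as low in the starved and EGF libraries, not in the DEX libraries. The test does not tell whether such a share entered as cells, RNA or reads.

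More genes passed with DEX (482) than with EGF (123) in MCF7, and GC and length trends, IMR90 RNA and a separate preparation of the DEX libraries were weighed against a wider DEX response. With GC and length trends removed the counts were 196 and 139, under the factor of 1.5 fixed for this explanation, so these trends fit by that rule. The rule counts calls alone. Among falls that lost the call, FOSL1 kept most of its change (−0.38 to −0.34) and SRF less (−0.33 to −0.21). How much of the excess the trends explain was therefore not settled. Without genes under 1% of the IMR90 level they were 384 and 120, which argues against IMR90 RNA as the whole cause; with both steps they were 86 and 136. The higher RNA45S5 share of the DEX libraries (1.497%) lay under the lowest of the other 4 MCF7 libraries (1.936%), but since each DEX library would be affected, this cannot be told from the treatment. A treatment that acts on genes by their GC content cannot be told from a trend of the libraries either.

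The 17 genes higher with both EGF and DEX in IMR90 were weighed as chance values of the shared starved libraries and as handling shared by both treated arms, against responses to each ligand. The highest overlap of unchanged groups in simulations was 1, against 17 seen. Noise was drawn independently for each gene and library, so few calls could arise and a low overlap was near certain. Trends that many genes of a library share were left out. The simulations therefore could not decide whether chance values of the starved libraries gave the overlap. The simulations held no response to either ligand. They could not tell how far chance values of the shared libraries add to the overlap when many genes respond. Of the 17 genes, 8 differed between EGF and DEX, fewer than the part fixed as evidence against shared handling, so the test could not tell. The labels list no library given vehicle for 60 min.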

How the results depend on the processing

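No call of a named gene turned its direction under an alternative. No list that passed did so with camera, the replicate block or GC and length trends removed. Lists were not tested again under the other alternatives. Of lists that did not pass, 3 turned with GC and length trends removed and 8 with camera (fry adjusted p of at least 0.687). More genes passed with DEX than with EGF in MCF7 (482 against 123), but fewer (86 against 136) with trends removed and without genes under 1% of the IMR90 level. Counts of calls changed by more than 1.5 times in the cases given here, and the cause was not tested, except where fewer libraries or genes entered the test. With edgeR (TMM, then RLE) EGF in MCF7 gave 260 and 253 genes in place of 123, DEX in MCF7 927 and 903 in place of 482, DEX in IMR90 69 and 68 in place of 43, and the line difference of EGF 114 and 109 in place of 54 (85 with DESeq2). The 6 libraries of a line alone gave 26 (EGF, MCF7), 37 (EGF, IMR90), 43 (DEX, MCF7), 23 (DEX, IMR90), 51 (EGF against DEX, MCF7) and 45 (EGF against DEX, IMR90; main counts 205 and 164). A minimum change of 1.5-fold gave 64 (EGF, MCF7), 141 (DEX, MCF7), 130 and 105 (EGF against DEX, MCF7 and IMR90). Without a filter DEX gave 287 in MCF7 and 27 in IMR90. Without a variance trend EGF gave 75 and DEX 146 in MCF7. Without the MCF7 DEX libraries DEX in IMR90 gave 26. With GC and length trends removed DEX in MCF7 gave 196, and without genes under 1% of the other line as well 86 (DEX, MCF7), 91 (EGF against DEX, MCF7), 105 and 38 (line differences of EGF and DEX). Without those genes alone the counts were 110 (EGF against DEX, MCF7), 84 and 39 (line differences of EGF and DEX). Leaving out 1 library gave 62 to 227 (EGF, MCF7), 115 to 831 (DEX, MCF7), 134 to 150 without a library compared and 313 without either starved library (EGF against DEX, MCF7), 26 (DEX, IMR90, without either MCF7 DEX library), 32 to 119 and 46 to 115 (line differences of EGF and DEX); the lone library of a group was then assumed to vary like the other groups.

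Of shared calls, EGF and DEX in MCF7 shared 15 higher genes without genes under 1% of the IMR90 level, and 98 lower with edgeR and 8 with trends removed; in IMR90 they shared 1 lower gene with edgeR and 1 with trends removed. Between lines edgeR gave 38 for EGF, higher; DESeq2 and edgeR gave 6 and 6 for DEX, higher, and 3 and 5 for DEX, lower, with 0 once trends were removed. The split of calls into higher and lower moved by more than 10 percentage points with edgeR scaling: 72.4% higher against 49.6% (EGF, MCF7), 45.2% against 35.1% (DEX, MCF7), 54.6% against 76.5% (EGF against DEX, MCF7) and 42.6% against 66.0% (line difference of DEX, where the larger side turned, as it did for EGF in MCF7). Other fits moved it too. For DEX in MCF7 the larger side turned to higher with trends removed (64.3%), without a variance trend (61.0%), at 1.5-fold or more (78.7%), with the 6 libraries of the line (53.5%) and without MCF7_starved replicate 1 or either DEX library (58.6% to 63.7%). For EGF against DEX in MCF7 it turned to lower with trends removed (49.7% higher), without a variance trend (48.3%), at 1.5-fold or more (40.8%) and without either EGF library (43.3% and 49.0%). It turned for the line difference of EGF without MCF7_starved replicate 1 (44.5%), and for that of DEX with DESeq2 (63.5%), a pseudocount of 5 (55.4%) and without genes under 1% of the other line (84.6%, or 81.6% with trends removed as well). The starved lines stayed between 11041 and 15228 in place of 13897. Of 88 list tests, 9 lost and 0 gained a call with an estimated correlation, 3 lost and 13 gained with the preset correlation, and 3 lost and 2 gained with trends removed. For EGF in MCF7, with 21.3 to 23.5 M reads and 2 libraries per group, limma recovered 60% of simulated 1.5-fold changes, so smaller responses may be missed there. The other comparisons were not simulated in this way. False limma calls in that simulation (26 of 192) exceeded the threshold and lay mostly under 10. In the data, limma calls with every compared group under 10 were 12 of 123 (EGF, MCF7), 23 of 107 (EGF, IMR90), 76 of 482 (DEX, MCF7) and 6 of 43 (DEX, IMR90). For EGF against DEX they were 58 of 205 in MCF7 and 24 of 164 in IMR90.

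Over all genes tested no effect shared by replicate number was seen: deviations of libraries with the same number correlated between −0.041 and 0.025 over 15 pairs of groups. Genes near 0 in a line entered these values, so an effect shared in fewer genes was not excluded. With a replicate block the counts were 100 and 90 (EGF, MCF7 and IMR90), 405 and 41 (DEX), 198 and 151 (EGF against DEX), 46 and 65 (line differences of EGF and DEX) and 13530 (starved lines); 3 list calls were lost and 2 gained, and 3 lists that did not pass turned their direction.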

Other observations

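Some genes moved in opposite directions with the 2 treatments; these were picked from the calls after their values were seen. In IMR90, IER2, IER3 and LIF rose with EGF (2.07 ± 0.08, 1.44 ± 0.12 and 1.42 ± 0.11) and fell with DEX (−0.55 ± 0.08, −0.71 ± 0.12 and −0.67 ± 0.11; adjusted p = 0.0143, 0.0358 and 0.0321). EGF and DEX differed by 2.62 ± 0.08, 2.15 ± 0.12 and 2.09 ± 0.11 for these genes. In MCF7, FOSL1, NAB2, SRF, MYADM and JUNB rose with EGF (1.80 ± 0.08, 1.42 ± 0.11, 0.51 ± 0.05, 0.60 ± 0.07 and 0.68 ± 0.11) and fell with DEX (−0.38 ± 0.08, −0.57 ± 0.11, −0.33 ± 0.05, −0.35 ± 0.07 and −0.47 ± 0.11; adjusted p = 0.0296, 0.0203, 0.00628, 0.0203 and 0.0499). The falls with DEX of these 8 genes each lost the call without at least 2 of the 4 compared libraries (adjusted p up to 0.198 in IMR90 and 0.223 in MCF7). With GC and length trends removed none of the 5 falls in MCF7 was called (−0.34 ± 0.08, −0.46 ± 0.12, −0.21 ± 0.06, −0.30 ± 0.06 and −0.38 ± 0.13; adjusted p = 0.0566, 0.0903, 0.121, 0.0526 and 0.179). In IMR90, IER2 and IER3 stayed called and LIF did not (−0.65 ± 0.12, adjusted p = 0.0542).

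Reads on replication-dependent histones were 0.0612% to 0.0669% of reads in the MCF7 libraries and 0.0366% to 0.0411% in the IMR90 libraries.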
